A study of Mus musculus with 8 samples.

How the data were processed

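RNA-seq was carried out on whole perigonadal adipose tissue of 4 wild-type mice and 4 mice with an adipocyte-specific gene knockout, described in the labels as age- and weight-matched. RNA was extracted with a commercial column kit and sequenced on a HiSeq4000, per the labels' protocols. The deposited values are whole-number read counts per gene symbol, 1 table per mouse, which the authors made without normalization as far as the values show. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.0g1, featureCounts, Cufflinks and edgeR and the mm10 genome; the role of each and the strand setting of the counting are not given in the sources used here. Exon positions came from the authors' deposited merged gene annotation, in which 190 of 23212 symbols covered more than 1 locus, 38 lay on more than 1 chromosome and 2457 shared exonic bases with another symbol. Reads in such shared bases cannot be assigned to 1 gene with certainty.

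Groups were taken from the labels. No pair of libraries within a genotype agreed within sampling noise, the smallest chi-square per degree of freedom being 63. Genes were kept with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 14493 genes. Libraries were scaled by TMM, with factors from 0.966 to 1.05, and knockout was compared with wild type by the quasi-likelihood F test with robust dispersion estimates and no covariate. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and the common biological coefficient of variation was 0.301. The SE of a log2 fold change is the one that the F statistic implies. Levels are given as CPM, counts scaled to a common library size, with the TMM-scaled library sizes. Because each library held 46444435 to 51431956 counts, counting error was small beside the common biological coefficient of variation for genes above a few CPM. Differences between mice therefore set the precision in general. An exception was Morf4l1, whose spread between mice was no larger than counting error.

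The 39 gene lists were fixed before the data were examined, together with the tests and the rule for named genes. Of these, 35 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Both were run only in the main fit with all libraries. List results in every other setting, such as with libraries left out, rest on the preset correlation of 0.01. Listed symbols were matched to older symbols where needed, 9 in all, such as Emr1 for Adgre1, and 5 listed symbols had no match. Single values per library were compared by a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.0286.

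The rule for named genes took corepressor complex members; the genes with the smallest p in each direction with non-overlapping groups, a mean of at least 1 CPM and a symbol of a named gene, up to 10 that pass or, where fewer than 5 pass, the 5 with the smallest p; up to 4 members of each list with the smallest p; 14 genes of adipocytes and macrophages given in every case; and the genes past the threshold with the largest changes. Genes outside the rule are said to have been chosen after their values were seen. The targeted gene is not reported here.

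The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of these 4 against 4 libraries. Each of 10 simulations changed 200 genes, taken from those at a mean of 1 CPM or more, and the first tested 14376 genes. On average, 61.8% of genes changed 2-fold and 88.4% of those changed 4-fold were recovered, and 5.55% of calls were false. The recovery rates do not cover genes below 1 CPM. Genes were drawn independently of each other, without the correlations of real tissue, so these rates may not hold for the real counts. Alternatives were median-ratio size factors, total counts, no low-count filter and a stricter one of 1 CPM in 4 libraries, the replicate number as a block, each library left out, DESeq2 1.42.0, limma voom, non-robust dispersion, and for lists the removal of members shared with another list. The removal of the pair of libraries with epithelial genes was added after the data were examined.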

Results

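RNA was sequenced from whole perigonadal adipose tissue of 8 C57BL/6 mice, 4 wild type and 4 with an adipocyte-specific gene knockout. The mice were 20 weeks old and had received a 45% fat diet for 12 weeks, starting at 8 weeks of age. Whole tissue holds adipocytes together with macrophages, lymphocytes, vessel cells, fibroblasts and mesothelium, so a transcript level reflects both expression per cell and the mixture of cells. The libraries held 46444435 to 51431956 counts each, and 14493 of 23212 genes had enough counts to be tested. Library totals did not differ between genotypes beyond the spread between mice (n = 4 each, exact permutation test p = 0.171). Xist was at 3 counts or fewer in every library and the Y-linked gene Ddx3y at 4669 counts or more, both genes looked up after the values were seen.

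Among genes of corepressor complexes, Tbl1xr1, a WD-repeat subunit of such complexes, was at 41.9 ± 2.32 CPM in wild type and 57.0 ± 3.96 CPM in knockout (SD, n = 4 each), a log2 fold change of 0.44 (standard error, SE, 0.085) that did not pass over all genes in the edgeR quasi-likelihood test (adjusted p = 0.908) and did when adjusted over the list alone (adjusted p = 0.00338). Ncor1, a nuclear receptor corepressor, was at 176 ± 36.3 and 166 ± 38.7 CPM, and the deacetylase Hdac3 at 76.6 ± 4.47 and 80.9 ± 5.88 CPM, in wild type and knockout. Ncor1 shares exonic bases with Ttc19, so its counts are less certain. As a whole, the list did not stand apart from other genes (camera adjusted p = 0.611).

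Across the transcriptome 2 genes passed an adjusted p of 0.05, both lower in knockout. Of these, Morf4l1 (chromosome 9, 90091669 to 90114820) encodes a chromodomain protein of histone acetyltransferase and deacetylase complexes. Morf4l1 fell from 23.7 ± 0.621 to 13.9 ± 0.374 CPM, a log2 fold change of -0.76 (SE 0.081, adjusted p = 0.0437), with all 4 knockout libraries below all 4 wild-type libraries. No gene rose past the threshold in edgeR, while DESeq2 called 17 genes, 8 higher and 9 lower, and limma voom called 0. At an unadjusted p under 0.05 there were 323 genes, 169 higher and 154 lower, where 725 would be expected by chance. Leaving out any of the 8 libraries left 0 genes past the threshold, and total-count scaling or no low-count filter also left 0.

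The other genes named here did not pass in edgeR. The naming rule took the 5 genes with the smallest p in each direction, those that passed included, among genes at 1 CPM or more that are not predicted loci and whose libraries did not overlap between genotypes, so that separation follows from how they were chosen. Gsta4, a glutathione transferase that conjugates products of lipid peroxidation, was at 22.8 ± 5.59 CPM in wild type and 61.2 ± 9.27 CPM in knockout (log2 fold change 1.43, SE 0.19, adjusted p = 0.196). It belongs to a family of similar genes, and reads shared with a relative cannot be separated in these counts. Bckdhb, a subunit of the enzyme that degrades branched-chain keto acids, was at 97.1 ± 9.57 and 164 ± 21.0 CPM (log2 fold change 0.76, SE 0.12, adjusted p = 0.494). The log2 fold changes of Zfp949, Hemk1 and Pth1r were 0.86, 0.78 and 1.04, with adjusted p of 0.713, 0.715 and 0.715. Pth1r is the receptor for parathyroid hormone and its related peptide. On the lower side, Nsg1, the complement component C6 and Bod1l had log2 fold changes of -0.95, -1.56 and -0.37, each with an adjusted p of 1. Morf4l1, Gsta4, Bckdhb, Zfp949, Hemk1, Pth1r, Nsg1, C6, Bod1l and Tbl1xr1 were among the genes called by DESeq2. Groups that did not overlap were seen in 209 genes, 1.44% of those tested, where chance gives 2.86%.

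**Figure D1:**
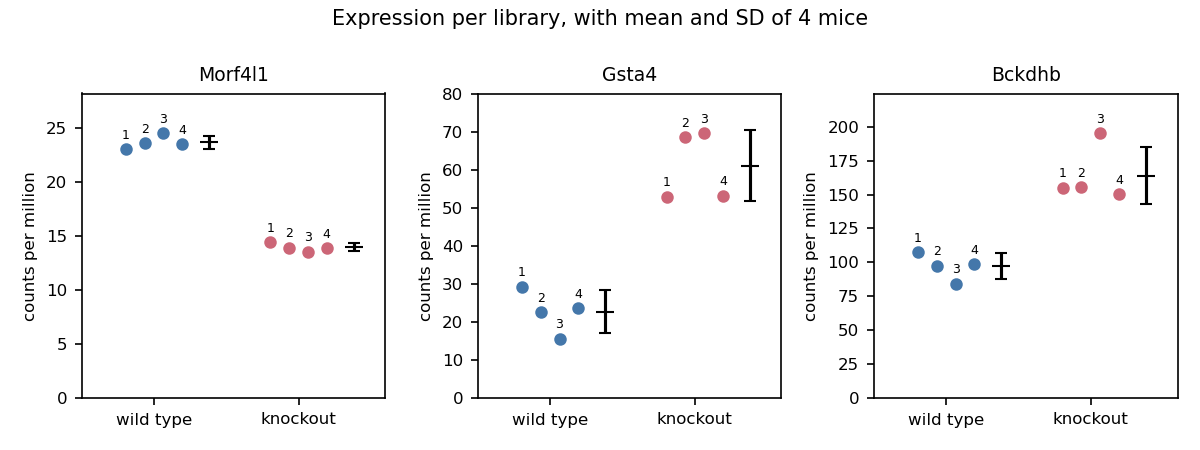
CPM (counts scaled to a common library size) of Morf4l1, Gsta4 and Bckdhb in each library, by genotype. Points are single mice with their replicate number, and the bar beside them is the mean with SD (n = 4). Morf4l1 was lower in all 4 knockout libraries, and Gsta4 and Bckdhb were higher in all 4 without passing the edgeR threshold.

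Genes and lists that describe the adipocyte did not pass in the main comparison, and some of these lists passed in other settings. Adiponectin (Adipoq) was at 5243 ± 1298 CPM in wild type and 5110 ± 1356 CPM in knockout, leptin (Lep) at 3478 ± 296 and 3102 ± 1078 CPM, and Pparg, the nuclear receptor that drives adipocyte differentiation, at 208 ± 21.2 and 214 ± 17.8 CPM. The adjusted p was 1 for all of these genes. Of the 20 mature adipocyte genes 11 had a log2 fold change above 0 and 9 below, and none passed either over all genes or adjusted over the list alone (camera adjusted p = 0.507). The median of that list was 0.014 and its mean -0.023. The list passed, in the lower direction, without knockout library 3 (adjusted p = 0.0319). Targets of PPAR gamma had an adjusted p of 0.7, and lipogenesis and triglyceride synthesis genes 0.701; the latter list passed, in the lower direction, without knockout library 2 (adjusted p = 0.00424) and without knockout library 2 and wild-type library 3 together (adjusted p = 0.00119). Scd1, the desaturase that makes monounsaturated fatty acids, was at 49600 ± 11420 CPM in wild type and 34070 ± 12730 CPM in knockout (log2 fold change -0.54, SE 0.32, adjusted p = 1). Lipolysis and fatty acid oxidation genes had 17 of 19 members above 0, with a median of 0.13 (adjusted p = 0.085, and 0.879 with an estimated correlation). That list passed as higher with total-count scaling (adjusted p = 0.0362), the stricter filter (adjusted p = 0.0476) or shared members left out (adjusted p = 0.0147), and without wild-type library 1 (adjusted p = 0.00123) or knockout library 4 (adjusted p = 0.000117). Its direction turned without wild-type library 3 and knockout library 2 together (adjusted p = 0.894). Of 13 thermogenic adipocyte genes 11 were above 0 (adjusted p = 0.0879), led by the muscle-type cytochrome oxidase subunits Cox8b and Cox7a1 with log2 fold changes of 0.69 (SE 0.18) and 0.59 (SE 0.21), neither of which passed. The thermogenic list passed in the higher direction without wild-type library 3 (adjusted p = 0.00323), wild-type library 4 (adjusted p = 0.0331), knockout library 1 (adjusted p = 0.0398) or knockout library 4 (adjusted p = 0.0217).

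The title of the series names adipose tissue macrophage phenotypes. General macrophage genes were higher in knockout as a list, with 19 of 20 members above 0 and a median log2 fold change of 0.65 (camera adjusted p = 0.00184), but no member passed over all genes or adjusted over the list alone. With an estimated correlation between genes the adjusted p was 0.879. Within the list, Ctss, a lysosomal protease, was at 99.8 ± 58.8 CPM in wild type and 228 ± 217 CPM in knockout, and Lgals3, encoding galectin-3, at 291 ± 80.4 and 494 ± 348 CPM. Cd68 was at 34.8 ± 22.3 and 65.2 ± 51.6 CPM, and Emr1, which encodes F4/80, at 38.8 ± 24.1 and 63.5 ± 47.7 CPM. These spreads came from differences between mice of 1 genotype: Cd68 was at 76.5, 24.4, 26.2 and 134 CPM in knockout libraries 1 to 4 and at 13.5, 23.1, 64.7 and 37.9 CPM in wild-type libraries 1 to 4. The list's call was lost without wild-type library 1 (adjusted p = 0.216), wild-type library 2 (adjusted p = 0.125) or knockout library 4 (adjusted p = 0.33).

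Neither macrophage polarisation list passed. Of 16 tested M1-type genes 10 were above 0 (adjusted p = 0.365), and of 21 M2-type genes 12 (adjusted p = 0.265). Itgax, which encodes CD11c, was at 18.1 ± 9.66 CPM in wild type and 49.2 ± 48.7 CPM in knockout, a log2 fold change of 1.44 (SE 0.73). Tnf was near the floor at 0.251 ± 0.0971 and 0.567 ± 0.337 CPM, and Il6, at 0 to 12 counts per library, was not tested. The M1-type genes Ccl2 and Nos2 were at 13.5 ± 15.1 and 9.87 ± 2.19 CPM in wild type and at 9.4 ± 4.1 and 10.3 ± 1.63 CPM in knockout; Ccl2 reached 36.1 CPM in wild-type library 2 and was at 3.79 to 7.91 CPM in the other wild-type libraries. Of the M2-type genes, Mrc1, which encodes CD206, was at 61.7 ± 39.4 and 71.9 ± 30.4 CPM, Retnla at 381 ± 183 and 369 ± 127 CPM, Arg1 at 0.811 ± 0.33 and 0.919 ± 0.426 CPM and Il10 at 0.165 ± 0.0988 and 0.309 ± 0.202 CPM. All of these tested genes had an adjusted p of 1. The M1-type list passed without wild-type library 3 (adjusted p = 0.0302), and the M2-type list passed without wild-type library 3 (adjusted p = 0.00116), wild-type library 4 (adjusted p = 0.0165) or knockout library 2 (adjusted p = 0.0379).

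Genes of lipid-associated macrophages, a lysosome-rich state found in obese fat, had 15 of 20 members above 0 with a median of 0.38 and did not pass (adjusted p = 0.067). Gpnmb was at 63.1 ± 48.7 CPM in wild type and 252 ± 253 CPM in knockout, Mmp12 at 44.1 ± 28.8 and 171 ± 193 CPM, Atp6v0d2 at 10.6 ± 9.79 and 36.8 ± 38.3 CPM, and Cd63 at 96.9 ± 11.9 and 126 ± 24.8 CPM. Gpnmb reached 352 and 563 CPM in knockout libraries 1 and 4, against 42.8 and 49.3 CPM in knockout libraries 2 and 3. The list passed with a stricter low-count filter (adjusted p = 0.0476), with shared members left out (adjusted p = 0.0147), and without wild-type library 3 (adjusted p = 0.0179), knockout library 2 (adjusted p = 0.0119) or knockout library 3 (adjusted p = 0.00261).

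**Figure D2:**
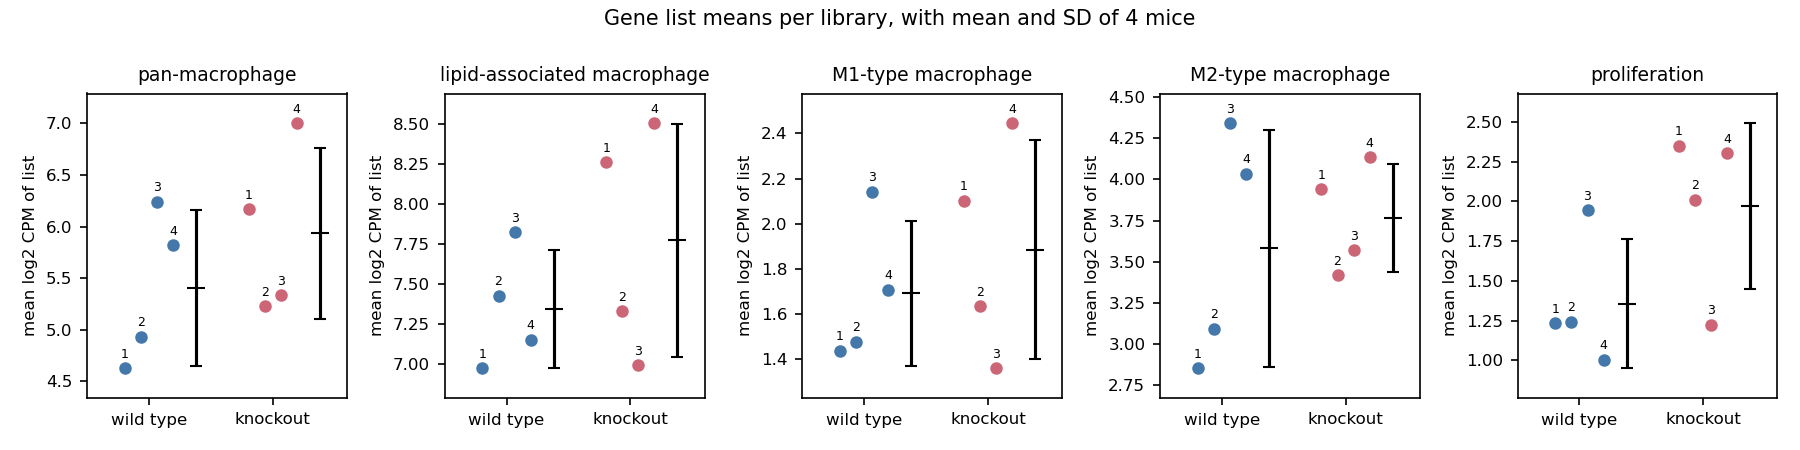
Mean log2 CPM of 5 gene lists in each library, by genotype, with the mean and SD (n = 4); the vertical axes do not start at 0. Knockout library 4 was highest of the 8 in the pan-macrophage panel, while knockout libraries 1, 2 and 3, at 6.17, 5.23 and 5.33, lay within the wild-type range of 4.63 to 6.24.

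Of 35 tested lists, 5 were called higher and 1 lower in knockout with the preset correlation, and 0 with an estimated correlation. Proliferation genes had the smallest p: all 16 were above 0, with a median log2 fold change of 0.67 (adjusted p = 1.06e-10, and 0.879 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at 6.91 ± 2.42 CPM in wild type and 11.3 ± 3.37 CPM in knockout, Tpx2 at 2.95 ± 0.912 and 5.43 ± 2.00 CPM, and Cdc20, whose exons share bases with Elovl1, at 1.82 ± 0.509 and 3.25 ± 1.05 CPM. No proliferation gene passed on its own, either over all genes or adjusted over the list alone. The list's call held without each library in turn, always with the preset correlation. Its mean log2 CPM per library gave an exact permutation p of 0.114, and knockout library 3, at 1.22, lay within the wild-type range of 1.00 to 1.94. Setting wild-type libraries 1, 2 and 4 and knockout library 3 against the rest gave an unadjusted camera p of 1.99e-24, against 3.03e-12 by genotype. MHC class II genes (9 of 10 above 0, adjusted p = 0.0227) and T and NK cell genes (18 of 19 above 0, adjusted p = 0.0242) were also higher, each with an adjusted p of 0.879 with an estimated correlation. Il7r was at 5.35 ± 3.32 and 15.9 ± 15.7 CPM, and Cd3d at 0.679 ± 0.284 and 1.29 ± 0.851 CPM, in wild type and knockout.

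The MHC class II call was lost without wild-type library 1 (adjusted p = 0.182), wild-type library 2 (adjusted p = 0.627) or knockout library 4 (adjusted p = 0.295), and with no low-count filter (adjusted p = 0.0716). That of T and NK cells was lost without wild-type library 1 (adjusted p = 0.216), wild-type library 2 (adjusted p = 0.483), knockout library 3 (adjusted p = 0.303) or knockout library 4 (adjusted p = 0.821), and with total-count scaling (adjusted p = 0.0658), no low-count filter (adjusted p = 0.156) or the stricter filter (adjusted p = 0.0601). Oxidative phosphorylation genes were all 25 above 0, by a median of 0.09 (adjusted p = 0.0405, and 0.879 with an estimated correlation). Their call was lost without wild-type library 1 (adjusted p = 0.0508), wild-type library 3 (adjusted p = 0.998) or knockout library 3 (adjusted p = 0.0707) and with no low-count filter (adjusted p = 0.156), and the list's direction turned without knockout library 2 (adjusted p = 0.624).

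Smooth muscle and pericyte genes were lower in knockout, 9 of 10 below 0 with a median of -0.47 (adjusted p = 0.0225, and 0.879 with an estimated correlation). Acta2, smooth muscle actin, was at 292 ± 212 CPM in wild type and 124 ± 12.5 CPM in knockout, and Mylk, the myosin light chain kinase, whose exons share bases with E130310I04Rik, at 155 ± 44.5 and 99.6 ± 10.2 CPM. Acta2 was at 605 CPM in wild-type library 2 and at 150 to 228 CPM in the other wild-type libraries, and its log2 fold change was -1.23 with all libraries and -0.59 without that library, with an adjusted p of 1 in both. The list's call was lost without wild-type library 3 (adjusted p = 0.144), wild-type library 4 (adjusted p = 0.0627), knockout library 1 (adjusted p = 0.206), or wild-type library 3 and knockout library 2 together (adjusted p = 0.0553). With all 8 libraries, endothelial cells had an adjusted p of 0.399, adipose progenitors and fibroblasts 0.357, mesothelial cells 0.123 and B and plasma cells 0.748. Endothelial genes passed as lower without wild-type library 2 (adjusted p = 0.00337) or knockout library 3 (adjusted p = 0.0319), and mesothelial genes as lower without wild-type library 4 (adjusted p = 0.000789) or knockout library 1 (adjusted p = 0.000849). Progenitor and fibroblast genes passed as higher without wild-type library 3 (adjusted p = 0.0402) and without wild-type library 3 and knockout library 2 together (adjusted p = 0.0181). Extracellular matrix genes had 18 of 20 members above 0 (adjusted p = 0.0916), with the collagen gene Col6a3 at 119 ± 32.4 and 196 ± 40.8 CPM. That list passed as higher without wild-type library 3 (adjusted p = 0.00116), knockout library 2 (adjusted p = 0.000429), knockout library 3 (adjusted p = 0.0319) or the first 2 of these together (adjusted p = 1.79e-06). Over the 35 lists, an exact permutation test of the mean log2 CPM per library gave a smallest p of 0.114 and a smallest adjusted p of 0.917.

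Wild-type library 3 and knockout library 2 differed from the other 6 in genes of epithelial and ciliated cells, chosen after the values were seen. Foxj1, a regulator of motile cilia, was at 7.97 and 26.1 CPM in this pair and at 0.287 CPM or less in the others. Epcam was at 5.79 and 19.6 CPM and Cuzd1 at 13.2 and 42.6 CPM, against at most 0.491 and 1.45 CPM. Without these libraries, a setting added after the values were seen, 0 genes passed, 11 lists were called higher and 3 lower, and the direction of the oxidative phosphorylation list turned (adjusted p = 0.00718). These list calls used the preset correlation, and no estimated correlation was run without these libraries. With the same preset correlation, regrouping all libraries across the genotypes called up to 20 lists.

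The genes with the smallest p lay close together in the genome. Of 11 genes with an unadjusted p under 0.001, 7 were on chromosome 9 between positions 78191966 and 110747145, where 0.614 would be expected from the 809 tested genes of that chromosome. They were Gsta4, Bckdhb, Zfp949, Hemk1 and Pth1r, higher in knockout, and Morf4l1 and the unnamed locus 9330159M07Rik, lower in knockout; the last was named after its values were seen and shares exonic bases with Trim43c. This region of 32.6 Mb, whose ends are set by the outermost of these genes, held 220 tested genes.

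**Figure D3:**
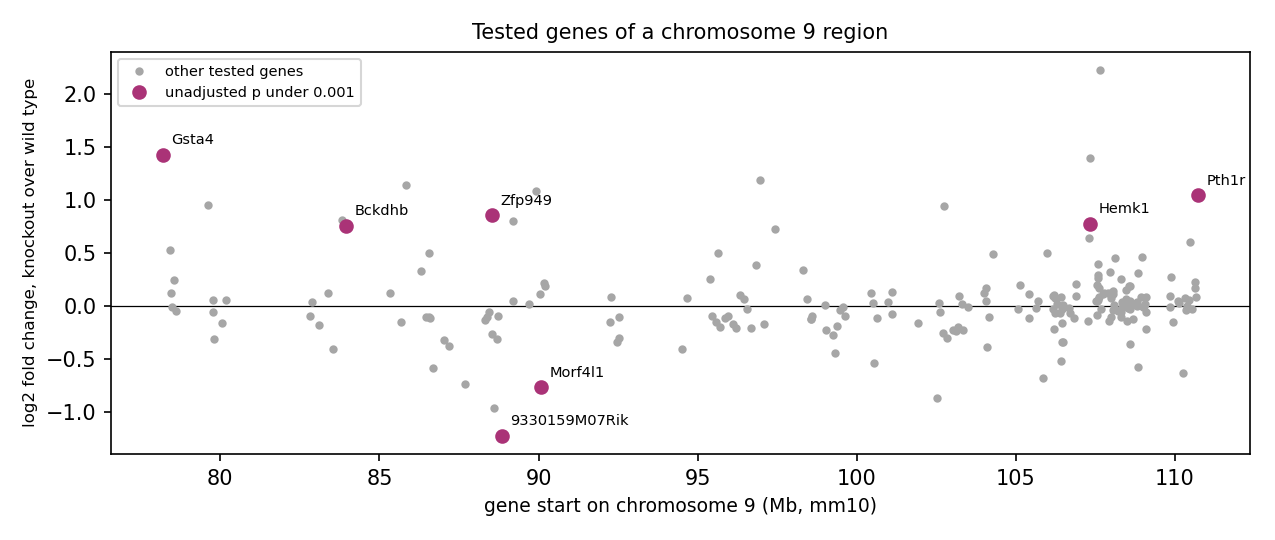
Log2 fold change of the 220 tested genes of the chromosome 9 region against the start of each gene in Mb (mm10). Coloured points are the 7 genes with an unadjusted p under 0.001, of which 5 lay above 0 and 2 below.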

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

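The tests of the whole chromosome 9 region, of overlapping genes, of a linked segment and of the adipocyte share were chosen after the results were seen. Among 156 groups of 4 libraries examined, 5 held a library far from the other 3, where chance alone gives about 7.8. Bckdhb was at a log2 CPM of 7.61 in knockout library 3 and at 7.23 to 7.28 in the other knockout libraries. The mean log2 CPM of the lipogenesis and triglyceride synthesis list was 8.93 in wild-type library 2 and 8.17 to 8.21 in the other wild-type libraries. That of the LXR target list was 8.56 in wild-type library 2 and 8.81 to 8.85 in the others. The thyroid hormone target list, which shares Fasn and Me1 with other lists, was at 6.84 in knockout library 2 and at 6.16 to 6.26 in the other knockout libraries. The retinoic acid target list was at 5.04 in knockout library 1 and at 4.78 to 4.79 in the others.

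Of the 10 genes with the smallest p, 7 lay on chromosome 9. Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many on a single chromosome. Any other split gave at most 4. The real split is always among the 35, so 1 is the fewest possible, and the pattern was first seen in these same data. The splits argue against chance without excluding it. A gain or loss of the whole region would move its genes together, but the median log2 fold change of its 220 tested genes was 0.0087, with quartiles of -0.12 and 0.12. Reads shared between overlapping neighbours among the 7 genes with an unadjusted p under 0.001 are argued against by distances of at least 271 kb. A DNA segment linked to the knockout, from another strain or around a transgene, may carry regulatory variants acting in both directions. On the rest of the chromosome 0.17% of tested genes had an unadjusted p under 0.01, which decides nothing, since the region was drawn around the genes with the smallest p. The counts hold no genotypes, so this cannot be told apart from an effect of the knockout on these genes.

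The number of genes past the threshold was 2 in the real split and at most 1 in any other of the 35. Only 1 split, the real one, gave as many, which is the fewest possible. For the count, chance is argued against but not excluded. The number of gene lists called was 6 in the real split, while 30 of the 35 splits gave as many and the highest of the others gave 20, so chance cannot be excluded for the list calls. Most of the other splits called more lists than the real one. This may reflect a structure among the mice other than genotype, or the preset correlation with which all splits were tested. With an estimated correlation the real split called 0 lists, and the other splits were not tested in that way. A lower share of adipocytes would raise macrophage and endothelial genes alike; the difference between these lists did not settle this (exact permutation test p = 0.371). The pan-macrophage call held in 5 of the 8 fits that leave out 1 library, so the call depended on single mice, and the M1-type minus M2-type difference was -1.89 ± 0.443 in wild type and -1.88 ± 0.228 in knockout (SD, n = 4 each, exact permutation test p = 1), which does not exclude a shift between macrophage types with genotype.

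Near Adipoq on chromosome 16, and named after their values were seen, Rfc4 and Eif4a2, which share exonic bases, had log2 fold changes of 0.61 and 0.52, Kng2 and St6gal1 had 0.15 and -0.03, and none passed over all genes. Rfc4 was at 6.16 to 6.98 CPM in wild type and 7.35 to 12.2 CPM in knockout, without overlap, with an adjusted p of 1 in edgeR. How the knockout was made, and whether the wild-type mice carried a recombinase, is not given in the sources used here, and the reason for these values is left open.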

How the results depend on the processing

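The setting without the pair of libraries with epithelial genes was added after the data were examined; all others were planned. Genes past the threshold numbered 2, both lower, and the same 2 genes passed with median-ratio factors, the stricter filter and non-robust dispersion. There were 0 with total counts, no filter, limma voom, the epithelial pair left out and each library left out (0 in each), and 17 with DESeq2 (8 higher, 9 lower). At an unadjusted p under 0.05 these settings gave between 243 and 805 genes. Morf4l1 was lower in every setting, with a log2 fold change between -0.78 and -0.75 with 1 library left out (adjusted p from 0.144 to 0.357) and -0.74 without the epithelial pair (adjusted p = 0.489). Its adjusted p was 0.119 with total counts, 0.0538 with no filter and 0.0608 with limma voom. DESeq2 called it, with an adjusted p of 5.95e-17. Fewer libraries leave fewer residual degrees of freedom; for the other settings the cause was not tested.

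With the replicate number as a block, 0 genes passed, Morf4l1 had a log2 fold change of -0.76 (adjusted p = 0.77), Retnla turned to 0.017, and 5 lists were called higher and 2 lower. The labels do not say whether the numbers pair the mice. Deviations of same-numbered mice correlated at 0.12, -0.015, -0.32 and -0.017, and no library correlated best with its own number. These correlations gave no sign of pairing but cannot exclude it. Wild-type library 2 and knockout library 2 together stood outside the other libraries in 20.6% of tested genes, where chance gives 7.14%.

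Lists called higher numbered 5 and lower 1. There were 2 higher with no filter, 0 and 0 with an estimated correlation or fry, 11 and 3 without the epithelial pair, and 2 to 12 higher and 0 to 3 lower with 1 library left out. The adjusted p of the pan-macrophage list was 0.879 with an estimated correlation and 0.96 with fry. With the preset correlation, its adjusted p was 2.71e-08 without the epithelial pair and from 1.09e-06 to 0.33 with 1 library left out. That of the lipid-associated macrophage list was 0.0476 with the stricter filter, 0.0147 without shared members, 0.00517 without the epithelial pair and from 0.00261 to 0.614 with 1 library left out. That of the M1-type list was 0.02 without the epithelial pair and from 0.0302 to 0.953 with 1 library left out; of the M2-type list 0.000177 and from 0.00116 to 0.882, with its direction turned without wild-type library 1 or 2; and of the mature adipocyte list from 0.0319 to 0.982 with 1 library left out, its direction turned without wild-type library 1 or knockout library 4. The oxidative phosphorylation list turned to lower without the epithelial pair (adjusted p = 0.00718) and had an adjusted p from 2.15e-05 to 0.998 with 1 library left out. The cause was not tested.

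Of 42 named genes, 9 changed direction in at least 1 setting, none of them called. With 1 library left out, log2 fold changes ranged from -0.25 to 0.065 for Ncor1, -0.013 to 0.11 for Pparg, -0.20 to 0.15 for Adipoq, -0.36 to 0.0079 for Lep, -0.12 to 0.58 for Mrc1, -0.077 to 0.36 for Arg1, -0.27 to 0.17 for Retnla, -0.83 to 0.64 for Ccl2 and -0.051 to 0.16 for Nos2. Without the epithelial pair Adipoq was at 0.0088, Lep at 0.059 and Retnla at 0.28, and with limma voom Retnla was at 0.030. The cause was not tested.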

Other observations

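Wild-type library 2 and knockout library 2 shared a lipogenic profile that crossed the genotypes; the genes here were chosen after their values were seen. Fatty acid synthase (Fasn) was at 7600 and 9530 CPM in these libraries and at 1400 to 2380 CPM in the other 6. Acly, which makes cytosolic acetyl-CoA, was at 1320 and 1510 CPM against 182 to 278 CPM, the NADPH-producing enzyme Me1 at 1240 and 1450 CPM against 275 to 438 CPM, and the elongase Elovl6 at 113 and 101 CPM against 20.4 to 32 CPM. Pdk4, which restrains glucose oxidation, went the other way, at 44.2 and 31.1 CPM against 67.5 to 149 CPM, as did the clock gene Per1, at 53.7 and 60.6 CPM against 98.1 to 127 CPM. Over all 28 pairs of libraries, this pair stood outside the other 6 libraries in the most genes, 2982 or 20.6% of those tested, where chance gives 7.14%. Wild-type library 1 with knockout library 3 followed at 2844 genes, and the lowest pair, wild-type library 4 with knockout library 1, had 374. No biological explanation was tested, as the labels give no feeding state or time of collection.

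Nnt, the mitochondrial transhydrogenase, also chosen after its values were seen, was at 41.7 ± 14 CPM in wild type and 24.8 ± 2.76 CPM in knockout (SD, n = 4 each), with all knockout libraries below all wild-type libraries and an adjusted p of 1 in edgeR. Red blood cell genes, with 4 tested members and therefore no list test, were all below 0 in knockout, with a median log2 fold change of -0.92. Their mean log2 CPM per library overlapped between genotypes (exact permutation test p = 0.229). Knockout library 4, at 3.83, lay above wild-type libraries 1 and 3, at 2.91 and 3.37, and wild-type library 2 was highest at 5.11.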
